A study of Gossypium hirsutum and Gossypium barbadense with 6 samples.

How the data were processed

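Single-cell RNA sequencing of protoplasts released from the surface of cotton ovules was analysed in 6 libraries, with 1 library per group. TM-1, the standard line of upland cotton (Gossypium hirsutum), was sampled on the day of anthesis (0 days post-anthesis, DPA) and at 1 and 2 DPA. N1N1, a G. hirsutum mutant, was sampled at 0 and 2 DPA, and the 3-79 line of G. barbadense at 2 DPA. Per the labels' protocols, ovules were treated briefly with cell wall-degrading enzymes, protoplasts were recovered by flotation, and libraries were made with a droplet kit that reads the 3' end of transcripts.

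The deposited values were counts of unique molecular identifiers (UMIs) per gene and barcode, made with Cell Ranger 6.0.0 per the file headers. Seurat was also named in the submitters' processing notes, without a role. The deposited barcodes had already been called as cells, and the rule used was not given in the sources used here. The feature list of the G. hirsutum libraries held 75376 cotton genes with the ID suffix v2.1 and 27416 genes with the suffix TAIR10, the Arabidopsis thaliana annotation release. The G. barbadense list held 74561 cotton genes with the suffix v1.1. None of the cotton IDs was found in the reference gene table at hand, so no gene could be given a name. The gene lists and cell type markers fixed before the data were examined could therefore not be looked up, and their medians were not computed. Clusters stayed numbered and unnamed. The chromosome was read from the gene ID.

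All sums and detected-gene numbers were taken over cotton genes, because the Arabidopsis genes had not been foreseen in the design, a choice made after the files were seen. Barcodes with at least 500 detected cotton genes were kept. Counts were summed over these barcodes per library and scaled by the library's sum of cotton UMIs to the usual counts-per-million unit (CPM). With 1 library per group the spread within a group could not be estimated, so no test between groups was run and no p-value was computed. Ratios of 2 libraries were given with an exact 95% interval (conditional binomial, Clopper-Pearson), and shares with an exact 95% binomial interval. For a share of 0 the limit given is 3 counts of the total. Intervals and limits cover counting error only, so they describe these libraries and not the conditions. A gene counted as 2-fold apart when the ratio was at least 2 in either direction, its interval excluded 1, and the higher library reached 50 CPM. As a check of the code, libraries were simulated from the real sums for the comparison of TM-1 1 DPA with 0 DPA, over 60581 genes. Each fold was set in 50 genes above the CPM minimum. This rule found 100% of genes set 3-fold, 4-fold or 8-fold apart and 0% of those set 1.5-fold apart. The simulation held counting error only, so at these depths its outcome follows from the rule, and it says nothing about the spread between libraries. The named genes were the 12 highest and 12 lowest per comparison by the log2 ratio after adding 5 CPM to both libraries, among genes with at least 50 CPM in the higher one. As the IDs had no names, the first 2 per direction are printed.

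The 5 G. hirsutum libraries were clustered together with Seurat 5.3.0 in R 4.3.3 on log-normalised counts, with 2000 variable genes, 30 principal components, RPCA integration over libraries and Louvain clustering at resolution 0.5 with seed 1. The G. barbadense library was clustered alone. Scrublet, as included in scanpy 1.11.5, marked 1 barcode as a doublet in TM-1 1 DPA and 0 in each other library, so it has not worked here, and doublets were kept. Scaling factors came from edgeR 4.0.16 (TMM) and DESeq2 1.42.0 (size factors), and were used only as alternatives. Sets of genes chosen in 1 comparison were read in another that shares no library with it, for 5 pairs of comparisons, readings that were added after the data were seen. Each set's median log2 ratio was taken over its genes with at least 10 CPM in either library read and UMIs in both. It was ranked among the medians of 10000 random lists of the same size matched on mean CPM. The overlaps given for independent lists cover only genes that reached 50 CPM in both comparisons.

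Before the data were examined, the alternatives fixed for the gene counts were the 2 scalings, equal weight for each cell, no barcode filter, at least 1000 genes per barcode, a minimum of 10 or 100 CPM, the 50 most abundant genes left out of the sum, and cells thinned to 1000 UMIs. For clusters they were resolution 0.25 or 1, no integration, 15 principal components and at least 1000 genes per barcode. Added after the data were seen were Arabidopsis UMIs in the library sum, barcodes with over 20% of their nuclear UMIs on Arabidopsis genes left out, and deep barcodes alone (at least 5000 cotton UMIs and at most 20% Arabidopsis). Deep barcodes were also clustered with every gene 2-fold apart in any comparison left out of the variable genes. The class of clusters high in a pair of genes, described with the results, was also defined after the data were seen, and so was the reading of each of its clusters alone.

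The libraries held 30606279 UMIs (TM-1 0 DPA), 73445796 (TM-1 1 DPA), 70152247 (TM-1 2 DPA), 29095411 (N1N1 0 DPA), 65441449 (N1N1 2 DPA) and 19035461 (G. barbadense). These totals include UMIs on Arabidopsis genes. Cotton genes held 64882820 in TM-1 1 DPA and 60089383 in TM-1 2 DPA. At the smallest cotton total of a G. hirsutum library, 28742407 UMIs, 50 CPM stands on over 1000 UMIs. The spread between replicate libraries is unknown.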

Results

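Protoplasts from the epidermis of cotton ovules, which includes the cells that grow into fibers, were profiled by droplet RNA sequencing around the start of fiber growth. The design asks how expression moves over the first days after anthesis in the line TM-1, how the mutant N1N1 differs from it, and how another cotton species compares at 2 DPA. Each of the 6 groups had 1 library, so no difference below has a replicate check. The deposited files held 7345, 9038 and 5969 barcodes for TM-1 at 0, 1 and 2 DPA, 5977 and 10801 for N1N1 at 0 and 2 DPA, and 3890 for G. barbadense. After the filter on detected genes, 9004 and 5929 barcodes remained for TM-1 at 1 and 2 DPA, and all barcodes of the other 4 libraries. Over all deposited barcodes and with Arabidopsis UMIs counted, the median number of UMIs per barcode lay between 2232 in TM-1 0 DPA and 3136 in TM-1 1 DPA.

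Arabidopsis nuclear genes took 10.0% of all UMIs in TM-1 1 DPA and 12.5% in TM-1 2 DPA, against 0.0252% to 0.0482% in the other 3 G. hirsutum libraries. Arabidopsis mitochondrial genes took 1.32% in TM-1 0 DPA, 1.18% in N1N1 0 DPA and 0.757% in N1N1 2 DPA. In TM-1 1 and 2 DPA they took 0.751% and 0.571%, so their shares did not follow the nuclear ones. In TM-1 1 and 2 DPA 539 and 760 barcodes had over 50% of their nuclear UMIs on Arabidopsis genes, and 0 barcodes of the other 3 did. The labels do not mention Arabidopsis. Comparisons of TM-1 1 or 2 DPA with TM-1 0 DPA, and of N1N1 2 DPA with TM-1 2 DPA, therefore cross this divide, and batch and group cannot be told apart in them. The comparisons of TM-1 2 with 1 DPA, N1N1 0 DPA with TM-1 0 DPA, and N1N1 2 with 0 DPA lie within a side of it.

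**Figure D1:**
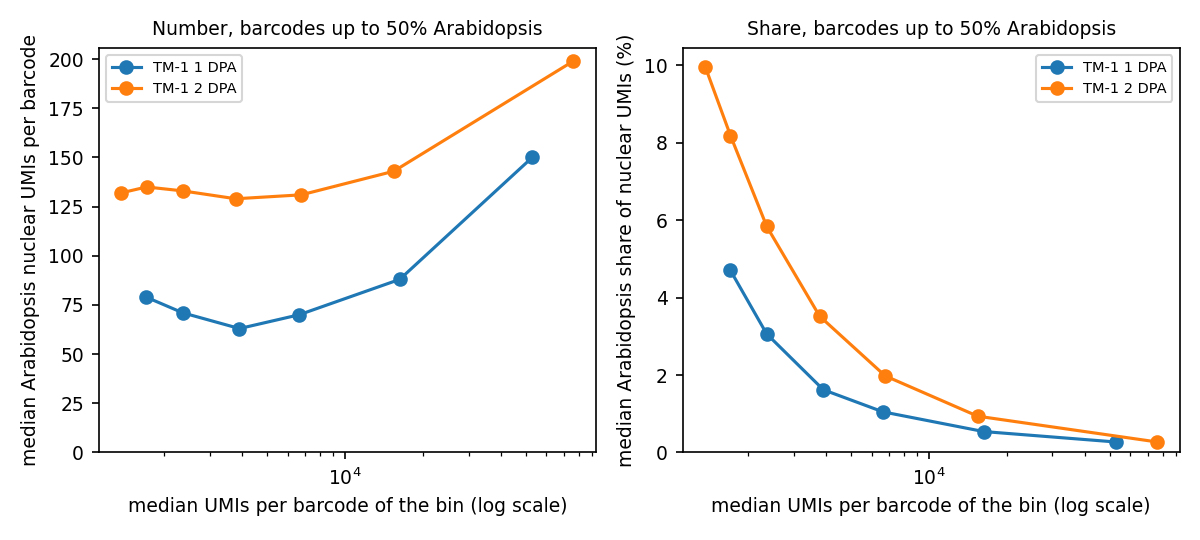
Median number (left) and median share (right, %) of Arabidopsis nuclear UMIs per barcode against the median UMIs of bins of barcodes (log axis), in the 2 libraries with Arabidopsis barcodes, leaving out barcodes over 50% Arabidopsis. In TM-1 2 DPA the median number was 132 in the lowest bin and 199 in the highest, and in TM-1 1 DPA 79 and 150, while the median share went from 9.97% to 0.270% and from 4.72% to 0.269%.

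Between 0 and 1 DPA in TM-1, Gohir.A06G172800 went from 0.663 to 136 CPM, 206-fold higher at 1 DPA (95% interval 133 to 337, on 20 and 8839 UMIs). Gohir.A10G147300 was 68.9-fold higher (53.9 to 89.6), at 146 CPM. Gohir.A03G176800 was 39.2-fold lower (32.0 to 48.6), at 1.5 CPM against 58.6, and Gohir.D09G049400 was 15.9-fold lower (14.2 to 17.9). Of 4852 genes with at least 50 CPM in either library, 2051 were at least 2-fold apart, 1299 of them higher at 1 DPA. Higher genes made up 63.3% of these, but 37.8% of 6398 genes at a minimum of 10 CPM, 51.6% with Arabidopsis UMIs in the library sum, and 89.8% and 89.4% with TMM scaling and DESeq2 size factors, which placed every log2 ratio 0.47 and 0.45 higher. With equal weight for each cell, 1235 genes were 2-fold apart and Gohir.A03G176800 was 15.5-fold lower, and with cells thinned to 1000 UMIs it was 18.5-fold lower and Gohir.A10G147300 38.4-fold higher.

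Between 1 and 2 DPA in TM-1, Gohir.D08G067300 was 14.6-fold higher at 2 DPA (13.9 to 15.2), at 481 CPM against 33.0. Gohir.A02G081503 was 12.4-fold higher (12.1 to 12.6), at 1912 CPM against 155. Gohir.A12G173100 was 229-fold lower (148 to 376), with 20 UMIs at 2 DPA, and Gohir.D11G345700 was 37.2-fold lower (31.7 to 43.9). Both of these lower genes had their highest TM-1 level at 1 DPA, since they stood at 15.4 and 18.3 CPM at 0 DPA and at 76.4 and 96.0 CPM at 1 DPA. That step from 0 to 1 DPA crosses the Arabidopsis divide. Deep barcodes held 4870 of the 4953 UMIs of Gohir.A12G173100 at 1 DPA, and 77.6% of all cotton UMIs of that library. Of 4534 genes, 1493 were at least 2-fold apart, and 350 of these (23.4%) were higher at 2 DPA. The balance depended on the scaling, as 64.5% of 2346 genes were higher with TMM and 77.4% of 2829 with DESeq2 size factors, which placed the log2 ratios 0.40 and 0.55 higher. With equal weight for each cell, 660 genes were 2-fold apart, and over the 10 alternatives Gohir.A12G173100 ran from 9.39-fold lower with cells thinned to 1000 UMIs to 2515-fold lower in deep barcodes (696 to 20773, on 2 UMIs at 2 DPA), Gohir.D11G345700 from 6.03-fold with equal weight for each cell to 58.7-fold in deep barcodes, and Gohir.A02G081503 from 6.69-fold to 18.1-fold higher.

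Over the whole interval from 0 to 2 DPA in TM-1, Gohir.A10G150200 was 167-fold higher at 2 DPA (155 to 181), at 3472 CPM against 20.8. Gohir.A06G172800 was 830-fold higher (537 to 1359), at 550 CPM. Gohir.D04G052900 was 36.2-fold lower (33.2 to 39.6), at 8.97 CPM against 325, and Gohir.A01G004800 was 130-fold lower (96.9 to 177). Of 5295 genes, 4193 were at least 2-fold apart, with 2094 higher and 2099 lower. Higher genes made up 49.9%, but 27.6% of 13532 genes at a minimum of 10 CPM, and 78.5% and 82.6% with TMM scaling and DESeq2 size factors, whose shifts were 0.87 and 1.007 on the log2 scale. With equal weight for each cell, 2568 genes were 2-fold apart, and over the 10 alternatives Gohir.A10G150200 ran from 118-fold to 336-fold higher, Gohir.A06G172800 from 472-fold to 1669-fold higher, Gohir.D04G052900 from 4.19-fold lower with thinned cells to 155-fold lower in deep barcodes, and Gohir.A01G004800 from 30.3-fold with equal weight to 524-fold lower in deep barcodes.

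**Figure D2:**
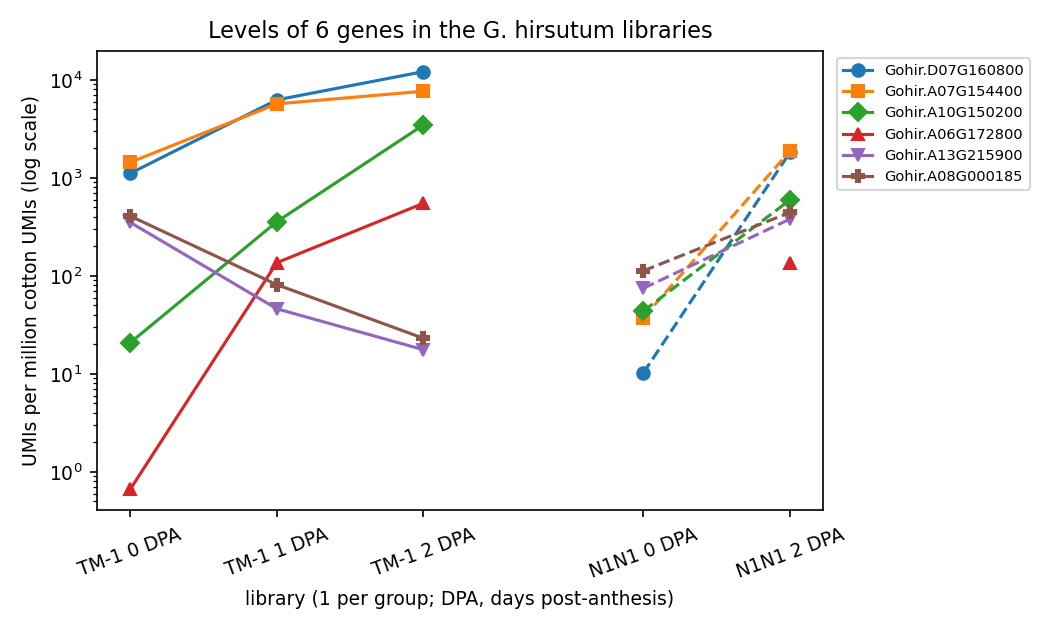
CPM of cotton UMIs (log axis) of 6 printed genes in the 5 G. hirsutum libraries, 1 point per library, with solid lines for TM-1 and dashed lines for N1N1; a library with 0 UMIs has no point. Gohir.D07G160800 stands at 1112 in TM-1 0 DPA, 12148 in TM-1 2 DPA, 10.2 in N1N1 0 DPA and 1817 in N1N1 2 DPA.

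At 0 DPA, N1N1 was set against TM-1 to find what differs in the mutant on the day of anthesis. The 2 genes lowest in N1N1 by the naming rule were Gohir.D07G160800, on chromosome D07, at 10.2 CPM against 1112 in TM-1, and Gohir.A07G154400, on chromosome A07, at 37.4 against 1441. The first was 109-fold lower (97.2 to 123) and the second 38.6-fold lower (36.3 to 41.0). Gohir.D08G058900 was 18.3-fold higher in N1N1 (16.3 to 20.6), at 179 CPM, and Gohir.A12G192200 was 85.9-fold higher (56.0 to 139), at 59.7 CPM. Of 4524 genes, 1010 were at least 2-fold apart, with 534 higher and 476 lower in N1N1. Higher genes made up 52.9%, but 42.5% of 3942 genes at a minimum of 10 CPM, 48.1% of 1177 with equal weight for each cell, 48.2% of 1190 with thinned cells, and 72.7% and 76.4% with TMM scaling and DESeq2 size factors, which placed the log2 ratios 0.19 and 0.24 higher. Over the 10 alternatives, Gohir.A12G192200 ran from 21.2-fold higher with thinned cells to 185.2-fold in deep barcodes, both on 8 UMIs in TM-1, and Gohir.D07G160800 was 71.5-fold lower with thinned cells.

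At 2 DPA, Gohir.D08G067300 was 107-fold lower in N1N1 than in TM-1 (95.4 to 121), at 4.5 CPM against 481, and Gohir.A06G051550 was 45.3-fold lower (37.0 to 55.9), at 1.49 CPM against 67.6. Gohir.A13G215900 was 21.5-fold higher in N1N1 (20.3 to 22.9), at 380 CPM against 17.6, and Gohir.A08G000185 was 19.2-fold higher (18.2 to 20.3), at 444 against 23.1. The gene pair Gohir.D07G160800 and Gohir.A07G154400 stood at 1817 and 1877 CPM in N1N1, against 12148 and 7667 in TM-1. Of 4980 genes, 3312 were at least 2-fold apart, with 1763 higher and 1549 lower in N1N1. Higher genes made up 53.2%, 31.9% with TMM scaling and 26.0% with DESeq2 size factors, which placed the log2 ratios at -0.53 and -0.70 relative to library-sum scaling, and 70.6% of 8855 genes at a minimum of 10 CPM but 46.9% of 1992 at 100 CPM. With equal weight for each cell, 1660 genes were 2-fold apart, 67.3% of them higher, and over the 10 alternatives Gohir.A13G215900 ran from 6.49-fold to 32.4-fold higher, Gohir.A08G000185 from 7.74-fold to 24.2-fold higher, Gohir.D08G067300 from 44.5-fold to 174-fold lower and Gohir.A06G051550 from 21.03-fold to 73.6-fold lower.

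The genes apart at 0 DPA were read at 2 DPA, in libraries not used to choose them. Of the 534 genes higher in N1N1 at 0 DPA, 167 were at least 2-fold higher and 9 at least 2-fold lower in N1N1 at 2 DPA. Only 198 of the 534 were among the 3334 genes considered at both ages. From those, independent lists would share 99.3 higher genes and place 39.3 on opposite sides. The set's median log2 ratio at 2 DPA, over the 431 genes that could be read, was 2.05, above all 10000 matched random lists. Of the 476 genes lower in N1N1 at 0 DPA, 161 were also lower at 2 DPA and 126 were higher, where independent lists would give 76.6 and 194 from the 386 considered at both ages. Their median log2 ratio was -0.04, at percentile 0.440 of the random lists. For the 459 such genes chosen and read in deep barcodes alone the median was 0.96, at percentile 99.97, so its direction was not settled.

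Within N1N1, the same gene pair ranked first among the genes higher at 2 DPA by the naming rule, which adds 5 CPM to both libraries, while other named genes had larger folds from lower levels. Gohir.D07G160800 was 178-fold higher than at 0 DPA (159 to 201) and Gohir.A07G154400 50.2-fold higher (47.3 to 53.4). Gohir.D06G210300 was 1587-fold lower at 2 DPA (1083 to 2430), with 26 UMIs against 18263, and Gohir.A02G131900 was 405-fold lower (325 to 513). Of 4784 genes, 1705 were at least 2-fold apart, with 1073 higher at 2 DPA. Higher genes made up 62.9%, 73.3% with TMM scaling and 68.0% with DESeq2 size factors, which placed the log2 ratios 0.15 and 0.07 higher. With thinned cells Gohir.D06G210300 was 724-fold lower, on 7 UMIs at 2 DPA.

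Genes that differed with age in TM-1 were read in N1N1, which shares no library with them. Of the 1299 genes higher in TM-1 at 1 than at 0 DPA, 713 were at least 2-fold higher in N1N1 at 2 than at 0 DPA and 10 were lower. Of the 1299, 952 were among the 3964 genes considered in both comparisons, and from those independent lists would share 248 and place 63.9 on opposite sides. The set's median log2 ratio in N1N1 was 1.31, above all 10000 matched random lists. Of the 752 genes lower at 1 DPA, 116 were lower in N1N1 and 95 were higher, where independent lists would give 40.9 and 159 from the 610 considered in both. For the 350 genes higher in TM-1 at 2 than at 1 DPA, 91 were higher in N1N1 and 7 lower, where independent lists would give 48.3 and 7.18 from the 160 considered in both. Of the 1143 genes lower in that interval, 102 were lower in N1N1 and 61 higher, where independent lists would give 48.8 and 328 from the 1087 considered in both. Over the interval from 0 to 2 DPA, 3909 genes were considered in both lines, of which 1228 were higher and 1858 lower in TM-1. Of these, 831 were higher in both lines and 233 lower in both, against 325 and 123 for independent lists. A further 111 genes were lower in TM-1 and higher in N1N1, and 8 the reverse, against 492 and 81.4 for independent lists.

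Joint clustering of the G. hirsutum barcodes gave 17 clusters. In 3 of them, clusters 1, 4 and 15, both genes of the pair Gohir.A07G154400 and Gohir.D07G160800 stood at least 2-fold above the other barcodes of the same libraries. These clusters held 10.2% of barcodes in TM-1 0 DPA (95% interval 9.49 to 10.9), 29.0% in TM-1 1 DPA (28.1 to 29.9) and 33.4% in TM-1 2 DPA (32.2 to 34.6). In N1N1 they held 3.20% at 0 DPA (2.76 to 3.67) and 18.0% at 2 DPA (17.2 to 18.7). Their part of all cotton UMIs was 17.0%, 56.9% and 81.1% in TM-1 at 0, 1 and 2 DPA, and 3.00% and 21.6% in N1N1 at 0 and 2 DPA. These parts moved with the clustering, as TM-1 2 DPA had 37.5% at resolution 1 and 30.1% in deep barcodes alone, TM-1 1 DPA 22.0% without integration, and N1N1 0 DPA 0.228% without integration, 1.49% with 15 principal components, 1.34% in deep barcodes alone and 1.51% in deep barcodes clustered without genes 2-fold apart. At 0 DPA, 5 of the 10 leading genes of cluster 1 and 4 of those of cluster 4 were at least 2-fold apart between the N1N1 and TM-1 barcodes of that cluster. At 2 DPA 1 and 0 were. These counts compare CPM within a cluster, without the interval, and do not say how the genes differed over whole libraries. The shares were also taken from deep barcodes clustered without any gene that was 2-fold apart over whole libraries in any comparison. The clusters were still picked by the level of the pair, which itself differed between the lines. Clusters high in the pair then held 14.95%, 39.8% and 64.2% of deep barcodes in TM-1 at 0, 1 and 2 DPA, and 2.24% and 13.96% in N1N1 at 0 and 2 DPA. Without integration the TM-1 share was 9.56% at 0 DPA and 9.50% at 1 DPA, and at resolution 1 it was 23.3% at 1 DPA and 22.5% at 2 DPA. Of the barcodes in the deep clusters high in the pair, the class held 66.2% without integration and 88.1% at resolution 1. In the main clustering it held 98.7%. Clusters that miss the pair rule can thus lower these shares, so flat shares do not show that the rise of such barcodes was lost. With 15 principal components the share in TM-1 1 DPA was 16.8%, and that in N1N1 0 DPA was 0.987%, or 0.100% without integration.

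**Figure D3:**
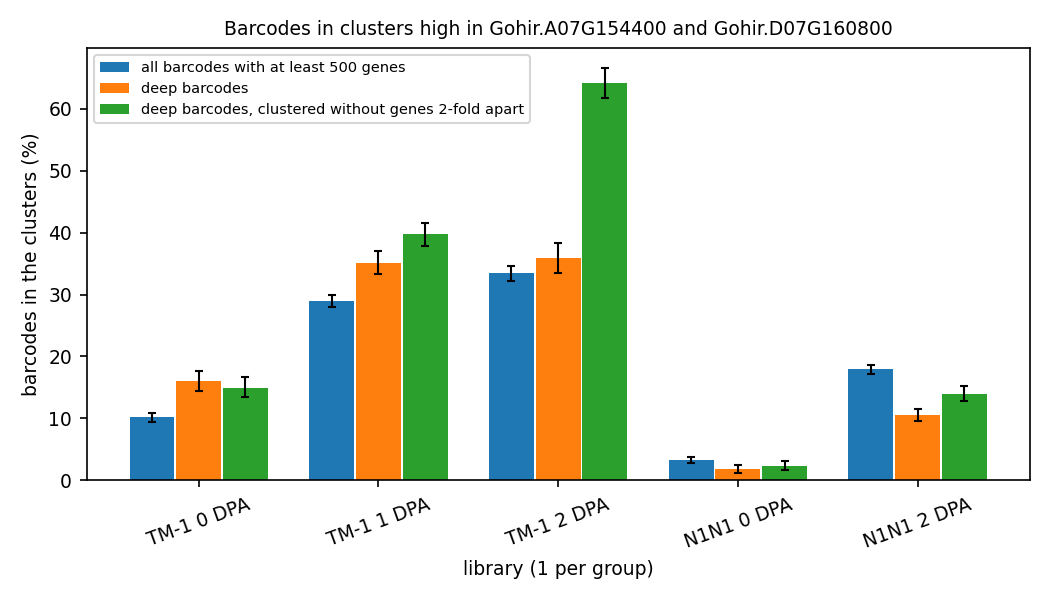
Percent of each library's barcodes in the clusters high in Gohir.A07G154400 and Gohir.D07G160800, for 3 clusterings, with exact 95% binomial intervals that cover counting error only. In each clustering both N1N1 bars stand below the TM-1 bar of the same age, as with 2.24% against 14.95% at 0 DPA in the clustering without genes 2-fold apart.

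With the deep barcodes clustered on all genes, the pair rule took in 2 clusters, and cluster 6 missed it because Gohir.A07G154400 was only 0.93 higher there on the log2 scale. The values for this clustering in TM-1 2 DPA, 35.9% of barcodes and 30.1% of cotton UMIs, therefore leave cluster 6 out. With genes 2-fold apart left out of the clustering, the same values were 64.2% and 86.6%. Cluster 6 had a median of 44214 cotton UMIs per barcode. It held 0.153% of deep barcodes in TM-1 0 DPA (0.0315 to 0.445), 5.70% in TM-1 1 DPA (4.85 to 6.65) and 26.4% in TM-1 2 DPA (24.3 to 28.7). In N1N1 it held 0 of 1699 at 0 DPA, which allows a share of up to 0.177% at 3 counts, and 2.67% at 2 DPA (2.15 to 3.26). Its leading genes were Gohir.A06G172800 and Gohir.A10G150200. Doublets could not be removed, and barcodes of so many UMIs can hold more than 1 cell.

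The clusters high in the pair had a different make-up in the 2 lines. At 2 DPA cluster 1 held 87.5% of their cotton UMIs in TM-1 and 45.6% in N1N1, where cluster 4 held 51.1%. At 0 DPA cluster 4 held 61.7% in TM-1 and cluster 1 held 55.4% in N1N1. These parts also follow the UMIs per barcode. Of the barcodes at 2 DPA, cluster 1 held 75.8% in TM-1 and 64.3% in N1N1, and cluster 4 held 16.8% and 34.4%. Of those at 0 DPA, cluster 1 held 44.2% and 71.7%, and cluster 4 held 40.2% and 25.7%. By barcodes, cluster 1 was thus the largest in both lines at both ages. Over these clusters together at 2 DPA, Gohir.D07G160800 stood at 6888 CPM in N1N1 against 14414 in TM-1, and Gohir.A07G154400 at 7403 against 9083. Taken 1 cluster at a time, Gohir.D07G160800 stood at 6203 against 14304 in cluster 1, 6952 against 12034 in cluster 4 and 15435 against 26652 in cluster 15, which held 25 and 147 barcodes. Gohir.A07G154400 stood at 5974 against 8486, 8058 against 10155 and 17099 against 24623. At 0 DPA the values over these clusters were 284 against 5633 for Gohir.D07G160800 and 986 against 7405 for Gohir.A07G154400. They were 117 against 5313 and 502 against 6454 in cluster 1, and 371 against 4315 and 1425 against 6076 in cluster 4, while cluster 15 held 5 N1N1 barcodes. In deep barcodes clustered anew, the 0 DPA values were 646 against 5610 and 2233 against 7502, so the folds went from 19.8 to 8.68 and from 7.51 to 3.36. With TMM scaling, the 2 DPA folds went from 2.09 to 3.18 and from 1.23 to 1.86. Of the 1549 genes lower in N1N1 at 2 DPA over whole libraries, 386 (24.9%) were also at least 2-fold lower over these clusters, 77.1% with TMM scaling, and 17.6%, 6.97% and 5.75% within clusters 1, 4 and 15 alone. Of the 1763 higher ones, 861 (48.8%) were also higher there, 40.3% with TMM scaling, and 41.1%, 10.5% and 19.0% within clusters 1, 4 and 15 alone. Both TMM shares keep the lists from library-sum scaling and rescale only the values within the clusters. Which of the 2 lists was shared more thus depended on the scaling.

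Cotton is an allotetraploid with an A and a D subgenome. Genes on D chromosomes took 50.4% of UMIs in TM-1 0 DPA, 50.5% at 1 DPA and 50.9% at 2 DPA. In N1N1 the share was 49.98% at 0 DPA and 50.6% at 2 DPA, and in G. barbadense 51.6%. The widest exact 95% interval was that of G. barbadense, 51.55 to 51.59%. Over clusters with at least 15 barcodes the share ran from 47.7% to 50.8% in TM-1 1 DPA and from 49.9% to 52.4% in G. barbadense. With the 50 most abundant genes left out, the G. barbadense share was 50.2%.

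G. barbadense 3-79 and TM-1 at 2 DPA were counted on different gene models, so no ratio per gene was formed. The most abundant G. barbadense genes were Gobar.D04G042100 at 9762 CPM and Gobar.D07G174000 at 9500 CPM, and those of TM-1 were Gohir.D07G160800 at 12148 and Gohir.A07G154400 at 7667. The 10 most abundant genes took 5.88% of UMIs in G. barbadense and 6.17% in TM-1 2 DPA, against 2.44% in N1N1 2 DPA. In G. barbadense 24.7% of barcodes were deep (23.4 to 26.1), and in TM-1 2 DPA 26.2% (25.1 to 27.4). Barcodes with at least 30000 cotton UMIs made up 1.95% (1.54 to 2.44) and 8.01% (7.33 to 8.73). Both TM-1 2 DPA shares are of 5929 barcodes, of which 4642 had at most 20% Arabidopsis. Clustered alone, the 3890 G. barbadense barcodes gave 9 clusters, the largest of which held 31.7% (30.3 to 33.2) at a median of 1269 UMIs. Cluster 1 held 19.9% of barcodes (18.6 to 21.2) and 45.4% of UMIs.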

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

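The tests of cotton reads counted on Arabidopsis genes were chosen after the result was seen, and the bounds of the other tests in this part were set before their values were seen.

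Arabidopsis nuclear genes took 10.0% of all UMIs in TM-1 1 DPA and 12.5% in TM-1 2 DPA, a signal outside the cotton measurement and far above the other 3 G. hirsutum libraries. Cotton reads counted on Arabidopsis nuclear genes would leave no barcode mostly Arabidopsis, but 539 barcodes in TM-1 1 DPA (5.96% of 9038, 95% interval 5.48 to 6.47) and 760 in TM-1 2 DPA (12.7% of 5969, 11.9 to 13.6) were. That test covers nuclear genes only. Mitochondrial genes took UMIs in all G. hirsutum libraries, and whether those are cotton reads was not tested. Among barcodes with at least 5000 UMIs, 5.67% in TM-1 1 DPA (4.89 to 6.53) and 3.93% in TM-1 2 DPA lay between 20% and 80% Arabidopsis, and the rest to either side. Both shares met the bound set for Arabidopsis cells in the droplets. Most of these barcodes lay below 20%, however, so low shares say little about mixing. In TM-1 1 DPA 182 barcodes lay between and 275 above 80%, and in TM-1 2 DPA 82 and 391. Barcodes above 80% are what Arabidopsis cells would give, but many others lay between 20% and 80%, more so in TM-1 1 DPA. Mostly Arabidopsis barcodes of TM-1 1 DPA held a median of 1280 cotton UMIs, enough to bring a barcode of 5000 UMIs under 80%. The barcodes between therefore do not show that droplets held cells of both species. Whether Arabidopsis cells were added on purpose or came from another sample is open, and no biological explanation was tested.

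Barcodes with few UMIs carried the highest Arabidopsis shares among barcodes up to 50% Arabidopsis. In TM-1 2 DPA the median share went from 9.97% in the bin of fewest UMIs to 0.270% in that of most. Mostly Arabidopsis barcodes in turn held a median of 1280 cotton UMIs in TM-1 1 DPA and 920.5 in TM-1 2 DPA, 81.4% and 75.7% of the medians of the other barcodes of cluster 0, consistent with RNA free in the suspension making up much of the cotton UMIs of low-UMI barcodes in these 2 libraries. Misassigned cotton reads would grow with the cotton UMIs, but barcodes with over 10000 UMIs had only 1.28 times the Arabidopsis nuclear UMIs of those with under 2000 in TM-1 1 DPA, at 12.4 times the total. The other 4 libraries have no such tracer, so their free RNA stays open.

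The age difference of a pair of genes went opposite ways in the 2 lines, and this was not tested. Gohir.A08G000185 was 17.7-fold lower at 2 than at 0 DPA in TM-1 and 3.95-fold higher in N1N1, a difference of 6.12 on the log2 scale. Gohir.A13G215900 was 19.9-fold lower in TM-1 and 5.09-fold higher in N1N1, a difference of 6.66. Both genes were printed because they ranked highest in N1N1 over TM-1 at 2 DPA, so much of each difference follows from that choice. The TM-1 libraries at 0 and 2 DPA also lie on different sides of the Arabidopsis divide, so age and batch cannot be told apart there.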

How the results depend on the processing

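Alternatives based on Arabidopsis UMIs, on deep barcodes and on genes left out of clustering were chosen after the results were seen, and the other alternatives were planned. No paired analysis was run, because each group had 1 library and the lines TM-1 and N1N1 shared only the ages 0 and 2 DPA. Alternatives without doublets were not run, as the doublet caller had not worked, and neither were those on gene lists, as no list could be looked up. Within the clusters high in the gene pair, no integration gave no value for the comparisons with N1N1 0 DPA. A count of genes was taken to have moved beyond 1.5 times the value reported, a share or ratio beyond its exact 95% counting interval, which is narrow, and a set median beyond 0.25 on the log2 scale. Of the values that answer a comparison, 80 alternatives stayed within these limits and 61 moved. All 240 ratios of the printed genes, for 24 pairs of gene and comparison under 10 alternatives, kept their direction and stayed at least 2-fold, though 96 moved beyond the counting interval. These genes were picked for extreme ratios in the same libraries, so this says little about genes with smaller ratios. Of the set medians 18 stayed, 1 moved and 1 reversed, both for the genes lower in N1N1 at 0 DPA when chosen and read in deep barcodes. Their median log2 ratio of N1N1 against TM-1 at 2 DPA went from -0.04 to 0.96, and that of TM-1 2 against 1 DPA from -0.07 (percentile 99.8 of random lists) to -0.74 (percentile 0.02). Of the parts of UMIs in the clusters high in the pair, and the ratios of the pair within them between N1N1 and TM-1, 42 moved beyond the counting interval, 3 stayed and none reversed. Except where stated, the cause was not tested.

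The number of genes 2-fold apart follows the CPM minimum by construction. In the order TM-1 1 against 0 DPA, TM-1 2 against 1, TM-1 2 against 0, N1N1 against TM-1 at 0 DPA, N1N1 against TM-1 at 2 DPA, and N1N1 2 against 0, it was 6398, 4651, 13532, 3942, 8855 and 4991 at 10 CPM, and 1188, 792, 2329, 474, 1992 and 866 at 100 CPM. For the TM-1 comparisons in that order and N1N1 against TM-1 at 2 DPA, it was 1235, 660, 2568 and 1660 with equal weight for each cell, and 1237, 650, 2419 and 1598 with cells thinned to 1000 UMIs. For TM-1 2 against 1 DPA it was 2346 with TMM scaling and 2829 with DESeq2 size factors. Within the clusters high in the pair, TMM scaling gave 2056 genes for TM-1 2 against 1 DPA and 2853 for N1N1 against TM-1 at 2 DPA, where library-sum scaling gave 1122 and 1390. No integration gave 3444 for TM-1 1 against 0 DPA and 361 for TM-1 2 against 1, where the main clustering gave 2259 and 1122.

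The share of barcodes in the clusters high in the pair, for TM-1 at 0, 1 and 2 DPA and N1N1 at 0 and 2 DPA, was 9.12%, 16.8%, 27.9%, 0.987% and 13.1% with 15 principal components. It was 15.97%, 35.2%, 35.9%, 1.77% and 10.5% in deep barcodes, and 14.95%, 39.8%, 64.2%, 2.24% and 13.96% in deep barcodes clustered without genes 2-fold apart. With at least 1000 genes per barcode, 25.9% in TM-1 1 DPA, 39.3% in TM-1 2 DPA, 2.16% in N1N1 0 DPA and 15.2% in N1N1 2 DPA were in them. Resolution 1 gave 23.3% in TM-1 1 DPA, 22.5% in TM-1 2 DPA and 15.4% in N1N1 2 DPA, and no integration 9.50% in TM-1 1 DPA, 29.4% in TM-1 2 DPA and 0.100% in N1N1 0 DPA.

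The D-chromosome share without the 50 most abundant genes was 50.31%, 50.09% and 50.32% in TM-1 at 0, 1 and 2 DPA, 50.31% and 50.50% in N1N1 at 0 and 2 DPA, and 50.19% in G. barbadense. In deep barcodes it was 50.32% in TM-1 0 DPA, 50.92% in TM-1 2 DPA, 49.87% in N1N1 0 DPA and 51.87% in G. barbadense. Depth limits counting error only, and the spread between libraries of a group is unknown.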

Other observations

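The tests in this part were chosen after the data were seen, and only the bound for clusters shaped by the genes that differ was set before its values were seen.

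Cluster 10 held 12.4% of barcodes in N1N1 0 DPA (95% interval 11.6 to 13.3), 2.07% in TM-1 0 DPA (1.76 to 2.42), 0.322% in TM-1 1 DPA, 0.911% in TM-1 2 DPA and 1.44% in N1N1 2 DPA. Its leading genes were Gohir.A05G361400 and Gohir.A03G181700. Of its barcodes 65.5% came from N1N1 0 DPA, so whether it is a cell type or a property of that library is open.

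The 534 genes higher in N1N1 than in TM-1 at 0 DPA were also read between 1 and 2 DPA in TM-1, in libraries not used to choose them. There 127 were at least 2-fold lower at 2 DPA and 12 higher, where independent lists would give 61.9 and 5.66 from the 165 considered in both comparisons. The median log2 ratio of the 534, over the 413 that could be read, was -1.63, below all 10000 matched random lists. Of the 476 genes lower in N1N1 at 0 DPA, 45 were lower at 2 than at 1 DPA in TM-1 and 21 higher, where independent lists would give 123 and 11.2 from the 327 considered in both. Their median was -0.07, at percentile 99.8 of the random lists, but for the 459 such genes chosen and read in deep barcodes alone it was -0.74, at percentile 0.02, so its standing among random lists was not settled.

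N1N1 had fewer barcodes than TM-1 in the clusters high in Gohir.A07G154400 and Gohir.D07G160800 at both ages. At 0 DPA N1N1 had 1.08 times the median UMIs per barcode of TM-1, which argues against lower depth. In addition, 0 barcodes of either library were mostly Arabidopsis, and their shares of all UMIs on Arabidopsis nuclear genes were only 1.41 times apart. Both values argue against the batch marked by Arabidopsis UMIs. At 2 DPA, where the N1N1 share was 53.8% of the TM-1 share, that batch and the genotype cannot be told apart, as the 2 libraries lie on different sides of it. Clustered without any gene 2-fold apart, the N1N1 share was 14.96% of the TM-1 share at 0 DPA and 21.8% at 2 DPA, but the clusters were still picked by a pair that is itself lower in N1N1, so clusters shaped by the genes that differ cannot be told apart from fewer such cells. The genotype, other differences between single libraries, and differences in which cells were released as protoplasts stay open and untested.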
